A study of Lactococcus cremoris subsp. cremoris MG1363 with 18 samples.

How the data were processed

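Total RNA was extracted with hot phenol, labelled with Cy3 by random priming and hybridised to 1-colour Agilent arrays, 1 array per sample, per the labels' protocols. The scanner files hold intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers: a processed signal (background-subtracted, spatially detrended, low values replaced by a positive surrogate), the median spot signal and the median local background. The deposited value table also holds intensity values on a linear scale; its 18 columns share 1 distribution (each median 62505.7), so they were quantile normalized, but how background was treated is not given in the sources used here. Its rows matched spots by feature number, with log-scale correlations across spots of 0.99 or more with the median signal.

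Each array had 15744 spots, of which 536 were controls. The others covered 2434 locus tags (2401 with 5 probes), 105 phage-labelled features, 581 rRNA, 231 tRNA and 404 pseudogene probes, and 5 probes of unexplained name that were not analysed. Processed signals were put on the log2 scale and each array's 75th percentile over non-control spots was subtracted. Spots with an outlier mark (100 to 1277 per array) were left out, spots of a probe were averaged, and then probes of a gene. In the comparisons with the reference, all probes had the sign of the gene's change for 95.6% to 98.9% of the called locus tags. A feature was tested if each array of at least 1 group had a probe of it well above background, not necessarily the same probe on each, which left 2515 features (2434 locus tags and 81 phage-labelled features). Spots with an outlier mark counted for this filter. Without such spots, llmg_phage_rep and llmg_phage_TP901-1p47 had no spot well above background in ethanol at 5 min. The bound given for the latter sets the brighter group's mean against, per ethanol array, the higher of the lowest signal well above background and the feature's own. Because probes of a feature differ in level, its mean also moves with which of them carry marks. No spot was marked saturated.

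One limma model (limma 3.58.1, R 4.3.3; lmFit, contrasts.fit and eBayes) was fitted over the 18 arrays and 7 groups without covariates, and Benjamini-Hochberg adjustment was applied within each of 18 contrasts at 0.05. The contrasts were 6 against the reference, 6 between alcohols at matched times, 3 between times and 3 interactions. All adjusted p-values of single features and probe classes come from this fit. Means of the rRNA, tRNA and pseudogene probes were tested as 3 rows of it, adjusted over these 3; the pseudogene mean passed in 0 of the comparisons with the reference. Intervals are 95% intervals of the fit. The design, the tests of the contrasts and lists, the rule for named genes and the alternatives were fixed before the data were examined, except those named as chosen later.

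The rule took the 6 largest rises and falls against the reference, the 4 largest each way for other comparisons and the 3 largest interactions, with adjusted p under 0.05 and, except for interactions, no overlap between the arrays of the groups. Chance gives such a lack of overlap in 10% of cases for 3 against 3, and more often where a group has 2 arrays. Because the files do not pair locus tags with names, at most the first 2 each way are identified per comparison, and members of the gene list are described by counts. A few features identified for one comparison are also given in others, chosen after their values were seen. Of 29 gene lists fixed beforehand 27 matched 0 features and were not tested. The cell envelope stress list matched 11 of 14 entries. The prophage list was taken as the phage-labelled features, a choice made after the feature names were seen. Their names do not state that they are prophages of MG1363. Lists were tested, adjusted over these 2, with camera (preset inter-gene correlation 0.01), an estimated correlation and fry; no list call held with an estimated correlation.

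Stretches are runs of at least 4 tags, next to each other in tag order on the array, all called in the same direction. The arrays lay on 3 slides, and slide and scan coincided: the first held the reference and replicate 1 of the 5 min groups, and the others held the remaining 5 min arrays and all 60 min arrays. Within-slide signs use arrays that also entered the fit, so they describe and do not test. The correlation between arrays of a slide was estimated as -0.08 for the random block. The alternatives were quantile, median and normexp processing (offset 50, on the median signal, since the scanner files used here hold no mean signal), the deposited values, 2 other filters, the brightest probe per gene, slide or replicate number as a block, fits of the compared groups alone, another empirical Bayes setting, stricter thresholds and leaving out each array. Chosen after seeing the data were fits without phage-labelled features, without 2 arrays of extreme signal range, with outlier marks ignored, and with each probe's offset from its gene removed before averaging, as well as the test of neighbouring calls.

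The fit was tested on simulated data with the real means and SDs of the 2515 features and 200 changed features per run. Noise was drawn independently for each feature and array, without correlation between genes, slide effects or scaling differences. The shares below therefore hold for such data and may not hold for the real arrays. For ethanol at 5 min against the reference it recovered 73.1%, 94.3% and 99.4% of features changed by 0.5, 1 and 2 on the log2 scale, and 5.4% of calls were false. For ethanol against butanol at 60 min it recovered 49.9%, 89% and 100%, with 3.8% false, and for the ethanol and butanol interaction 34%, 77.3% and 95.8%, with 5.6% false. Figures were drawn with matplotlib.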

Results

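Gene expression was measured in Lactococcus cremoris subsp. cremoris MG1363, a plasmid-free laboratory strain of a dairy lactic acid bacterium, before and after exposure to 1 of 3 alcohols. Exponentially growing cultures in a synthetic medium with 1% glucose and 2 µg/ml lipoic acid were sampled as the reference at an optical density (450 nm) of about 0.4. Ethanol at 55 mg/ml, butanol at 10 mg/ml or hexanol at 2 mg/ml was then added, and cells were collected after 5 min and 60 min. The samples include no untreated culture at 5 or 60 min. Differences from the reference and between times therefore cannot separate the alcohol from the time in culture. The 18 arrays comprised 3 of the reference, 3 of each alcohol at 5 min and 2 of each alcohol at 60 min, and the labels call the replicates biological. The label of replicate 2 of butanol at 60 min states 55 mg/ml where the growth protocol states 10 mg/ml, so the dose of that sample is unsettled. The number of arrays limits the precision: the fit had 11 residual degrees of freedom. The median signal of gene probes ranged from 36847 to 101791 between arrays, and at least 99.96% of gene probes were well above background on each array. Even the 1st percentile of gene probe signals was 55.9 to 397.3 times the median phage-labelled probe signal of the array. Whether part of the gene probe signal came from something other than transcripts was not tested. Any such part would make the fold changes below too small. Levels below are log2 signals minus the array's 75th percentile.

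Within groups, arrays correlated over locus tags with Pearson's r from 0.934 (hexanol 60 min) to 0.986 (reference), and genes are not independent replicates. The median within-group SD per gene was 0.116 in the reference and 0.175 in hexanol at 60 min. The files name protein-coding genes by locus tag and do not pair the tags with gene names. None of the 2434 tags was found in the RefSeq table used here, that of assembly ASM46895v1, which is of another strain (KW2) and not of MG1363. At most 2 features that rose and 2 that fell are therefore identified per comparison.

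**Figure D1:**
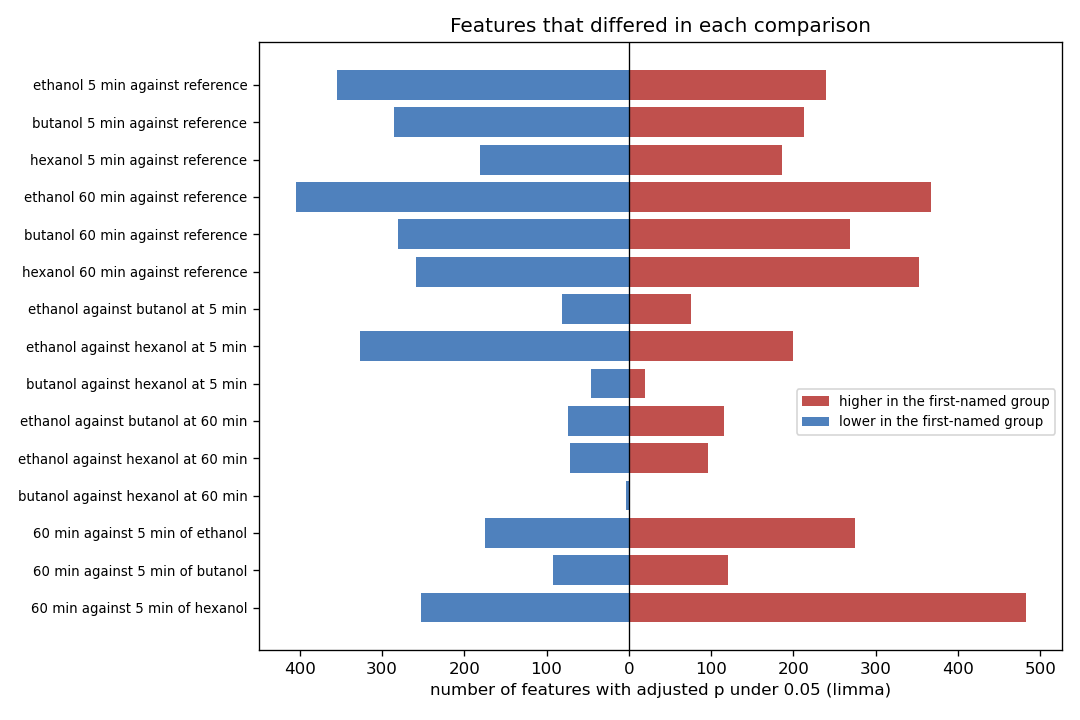
Number of features (locus tags and phage-labelled features) higher (red, right) or lower (blue, left) in the first-named group of each of the 15 comparisons, at an adjusted p under 0.05 in limma. Hexanol at 60 min against 5 min had the most higher calls (482), a split that turned under other processing, and butanol against hexanol at 60 min had 4 calls in all.

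The first comparison asked which transcripts responded within 5 min of ethanol. Of 2515 features tested, 594 changed, 239 higher and 355 lower, and 63 changed at least 2-fold. The largest rises were in the adjacent tags llmg_1172 and llmg_1171. llmg_1172 rose from -1.98 ± 0.14 (SD, n = 3) in the reference to 0.37 ± 0.18 (SD, n = 3), a 5.1-fold rise (log2 fold change 2.35, SE 0.123, limma adjusted p = 7.4e-09), and llmg_1171 rose 4.73-fold. Among falls, llmg_1509 decreased 2.52-fold (log2 fold change -1.33, SE 0.142, adjusted p = 6.3e-06). The phage-labelled llmg_phage_rep was also called lower (adjusted p = 0.041), but no fold is given: of its 5 probes, the 3 well above background carried outlier marks on all 3 ethanol arrays, and its ethanol level (-11.76; negative control spots -11.69) came from the others. With the marks ignored its log2 fold change was -0.34 (adjusted p = 0.54), and the adjusted p was 0.094 with probe offsets removed, 0.062 with quantile normalization, 0.25 in the deposited values, 0.99 with normexp correction and between 0.067 and 0.13 when any 1 of the 6 arrays was left out. A stretch of 6 consecutively numbered tags rose together by a mean of 1.55 on the log2 scale. A fit with slide as a block called 472 features, and on the single slide that held both groups all 594 had the same sign.

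After 5 min of butanol, 498 features changed, 213 higher and 285 lower, and 26 changed at least 2-fold. llmg_1490 rose 4.12-fold, from -1.2 ± 0.14 (SD, n = 3) to 0.84 ± 0.05 (SD, n = 3), with a log2 fold change of 2.04 (SE 0.119, limma adjusted p = 5.3e-08). llmg_0410 rose 3.37-fold. The largest falls were in llmg_0975 (log2 fold change -1.08, SE 0.143, adjusted p = 1.0e-04) and llmg_1000 (-1.06, SE 0.099). llmg_0975 lay in a stretch of 6 consecutive tags that all fell, by a mean of -0.89, and llmg_1000 in one of 5 that fell by a mean of -0.86. Blocking on slide gave 356 calls, and within the slide shared with the reference all 498 kept their sign. With normexp correction the split was 152 higher and 312 lower, with a median shift of all features of -0.12 against the main scaling.

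After 5 min of hexanol, 367 features changed, 186 higher and 181 lower, and 24 changed at least 2-fold. llmg_1490 again had the largest rise, 3.55-fold, to 0.62 ± 0.17 (SD, n = 3), with a log2 fold change of 1.83 (SE 0.119, limma adjusted p = 1.7e-07). llmg_1576 rose 3.45-fold, from 0.07 ± 0.12 to 1.85 ± 0.04 (SD, n = 3 each). The largest falls were in llmg_1146 (log2 fold change -1.25, SE 0.341, adjusted p = 0.021) and llmg_0987 (-1.21, SE 0.171, adjusted p = 2.5e-04). Their brightest probes alone gave -0.18 and -0.47, with adjusted p of 0.35 and 0.16, and the adjusted p of llmg_1146 was 0.063 with quantile normalization, 0.1 with normexp correction, 0.054 in the deposited values, 0.12 with slide as a block and 0.082 without reference replicate 1, 0.1 without hexanol replicate 2 and 0.051 without hexanol replicate 3. With outlier marks ignored llmg_1146 lay at -0.7 (adjusted p = 0.047) and with probe offsets removed at -0.47 (adjusted p = 0.15). In the fit that blocked on slide, 248 features were called, and all 367 kept their sign within the slide shared with the reference. With normexp correction 132 were higher and 78 lower.

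After 60 min of ethanol, 772 features differed from the reference, 367 higher and 405 lower, and 118 by at least 2-fold. llmg_2309 rose 5.93-fold, from -1.61 ± 0.15 (SD, n = 3) to 0.95 ± 0.12 (SD, n = 2), with a log2 fold change of 2.57 (SE 0.119, limma adjusted p = 4.0e-09). The adjacent llmg_2310 rose 5.18-fold. Both lay in a stretch of 6 tags that rose by a mean of 1.99. The largest falls were 3.85-fold in llmg_1508 (log2 fold change -1.95, SE 0.156, adjusted p = 4.0e-07) and 3.49-fold in llmg_0891, the latter in a stretch of 4 tags with a mean change of -1.36. The number of calls was 465 when slide was a block, and without ethanol replicate 2, 511. No slide held both the reference and a 60 min group, so this comparison and the other 2 at 60 min against the reference have no within-slide value.

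After 60 min of butanol, 549 features differed from the reference, 269 higher and 280 lower, and 51 by at least 2-fold. The largest rises were in llmg_1289 (3.64-fold, log2 fold change 1.87, SE 0.132, limma adjusted p = 1.8e-07) and llmg_1291 (3.59-fold). Both lay in the longest stretch found, 32 consecutive tags that all rose, by a mean of 1.05. llmg_0975 fell by 1.75 on the log2 scale (SE 0.16, adjusted p = 2.4e-06) and llmg_1000 fell by 1.74. A fit with slide as a block called 244 features, without replicate 1, 335, and without replicate 2, the sample whose dose label is unsettled, 282. Median scaling gave 195 higher and 327 lower.

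After 60 min of hexanol, 612 features differed from the reference, 353 higher and 259 lower, and 63 by at least 2-fold. llmg_2309 rose 3.99-fold (log2 fold change 2, SE 0.119, limma adjusted p = 7.1e-08) and llmg_2310 rose 3.75-fold, within a stretch of 6 tags that rose by a mean of 1.62. llmg_0976 fell 3.98-fold, from 1.41 ± 0.31 (SD, n = 3) to -0.58 ± 0.16 (SD, n = 2), and the adjacent llmg_0975 fell 3.89-fold. These lay in a stretch of 6 tags with a mean change of -1.65. The median of all features was 0.11 above the reference under the main scaling. Median scaling gave 159 higher and 364 lower and the deposited values 309 and 357. Blocking on slide gave 264 calls, and without reference replicate 1, 389.

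**Figure D2:**
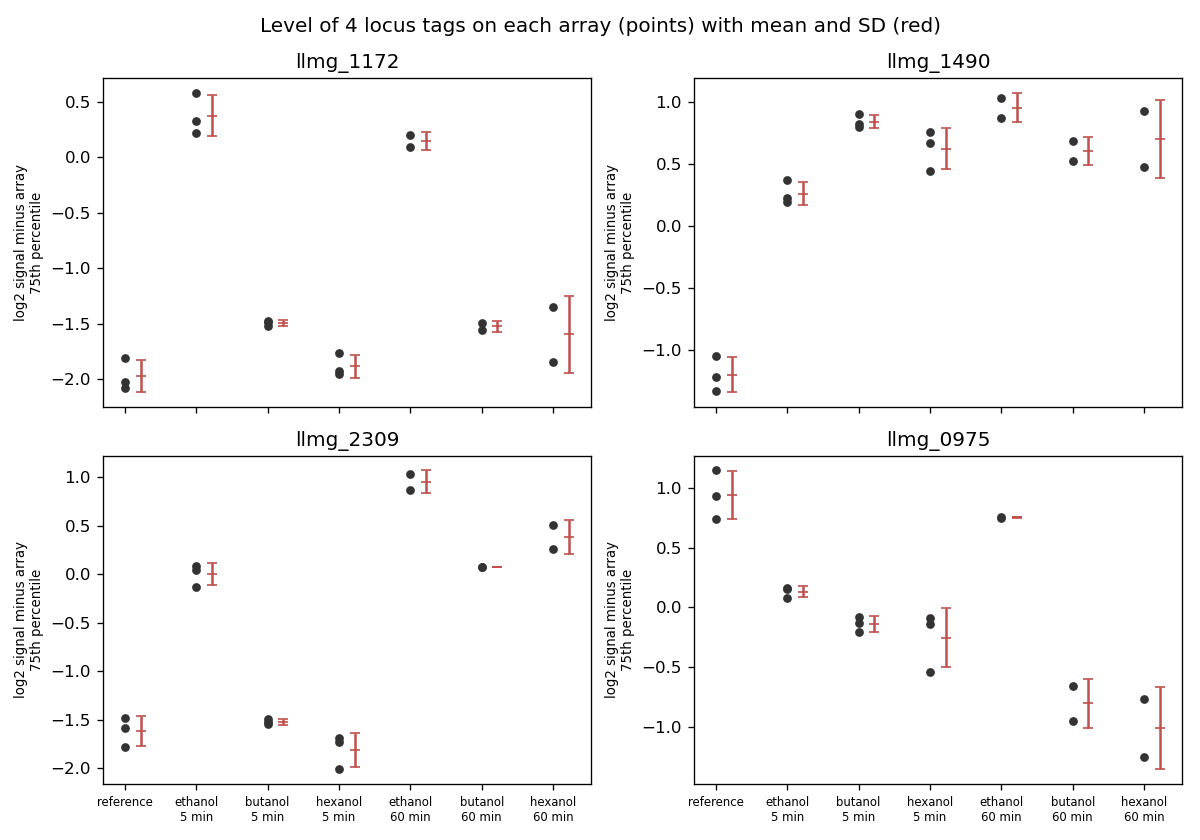
Level of 4 locus tags on each array (points, log2 signal minus the array's 75th percentile) in the 7 groups, with the group mean and SD in red. llmg_1172 was high in both ethanol groups, llmg_1490 was higher than the reference in all 6 alcohol groups, and llmg_2309 was high in ethanol at 5 min and in all 3 alcohols at 60 min.

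The calls of the alcohols overlapped. At 5 min, 91 features were higher and 113 lower with all 3 alcohols, and at 60 min 160 were higher and 184 lower. Across all 6 comparisons with the reference, 50 features were higher each time and 63 lower each time. Ethanol and butanol at 5 min shared 376 calls of the same direction and had 3 of opposite direction, where independent lists of these sizes would share 20.2 higher and 40.2 lower. Butanol and hexanol at 60 min shared 428 and had 0 opposite calls, against 37.8 and 28.8 for independent lists. All comparisons used the same 3 reference arrays. In 100 simulations of unchanged groups, array residuals were drawn at random with replacement for all groups, the reference included. The median number of shared calls was 0, although 1 simulation gave 1001 for ethanol and hexanol at 60 min. The 3 real reference arrays were not kept, so the simulations do not measure what sharing these particular arrays contributed. Across features, the covariance of log2 fold changes was 0.1259 for butanol and hexanol at 60 min against 0.0124 simulated, and 0.0384 for ethanol and hexanol at 5 min against 0.0108 simulated. The correlation of the latter pair across features (r = 0.33) did not exceed its simulated value (0.4), nor did that of hexanol at 5 and 60 min (0.37 against 0.43), while r was above the simulated value in the other 7 pairs compared. The reference had too few arrays to be split, so part of the excess may come from the shared controls. Changes with time in culture that the alcohol groups had in common would also count as overlap. Without an untreated culture at 60 min they cannot be told apart from a shared response to the alcohols.

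Calls lay next to each other along the locus tag numbering in 14 of the 15 comparisons, a test chosen after the data were seen. For ethanol at 60 min, 432 neighbouring pairs were called in the same direction, against a mean of 122.5 and a maximum of 162 in 10000 shuffles of the calls (permutation p = 1e-04, the smallest these shuffles can give). For hexanol at 5 min the number was 165, against a mean of 27.2. Stretches of at least 4 tags held from 30.7% (hexanol 5 min) to 44.9% (butanol 60 min) of the called tags in the comparisons with the reference. Butanol against hexanol at 60 min, with 4 calls, had 0 such pairs.

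Probes for tRNA genes, taken as 1 mean over 231 probes, were lower than the reference in each alcohol group. The mean fell by 0.37 with ethanol, by 0.42 with butanol and was -0.26 with hexanol at 5 min (limma p adjusted over 3 probe classes = 0.0092, 0.0042 and 0.076). The hexanol arrays at 5 min lay at 0.507, 0.084 and 0.526 against a reference mean of 0.64, so replicate 2 carried much of that difference. At 60 min the tRNA mean fell by 0.52, 0.39 and 0.44 with ethanol, butanol and hexanol (adjusted p = 0.0017, 0.015 and 0.0068). The sign was negative under each of the 4 other scalings and value sources in all 6 groups. With quantile normalization hexanol at 5 min passed (-0.3, adjusted p = 0.0091) and butanol at 60 min did not (-0.2, adjusted p = 0.15). Blocking on slide gave values of -0.3, -0.34 and -0.19 at 5 min (adjusted p = 0.065, 0.034 and 0.14) and -0.41, -0.28 and -0.33 at 60 min (adjusted p = 0.038, 0.2 and 0.11). The calls of ethanol at 5 min and of butanol and hexanol at 60 min thus ended with the block.

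Probes for rRNA fell by 0.57 after 60 min of ethanol (limma p adjusted over 3 probe classes = 0.035), and were lower at 60 than at 5 min of hexanol by -0.84 (adjusted p = 0.0067) and of ethanol by -0.62 (adjusted p = 0.049). With quantile normalization these values were -0.02, -0.01 and -0.01, and in the deposited values, also quantile normalized, -0.01 each. The median rRNA probe lay 2.069 to 3.616 above the median gene probe (log2) on each array. Giving all arrays 1 distribution largely fixes the level of such bright probes, so those values near 0 decide nothing about rRNA. Median scaling gave -0.6, -1.04 and -0.67 (adjusted p = 0.06, 0.0044 and 0.073) and normexp correction -0.48, -0.83 and -0.57 (adjusted p = 0.12, 0.017 and 0.13). Blocking on slide gave -0.32, -0.75 and -0.53 (adjusted p = 0.36, 0.011 and 0.079). Hexanol at 60 min passed against the reference with median scaling alone (-0.64, adjusted p = 0.044). Unscaled median rRNA signals were 434099 to 439131 in the reference. At 5 min they were 398008 to 521179 in ethanol and 417514 to 573616 in hexanol. At 60 min they were 422467 and 437060, and 465334 and 499744. The 75th percentile averaged 89177, 87865, 80393, 128102 and 135528 in these groups, so the rRNA falls are relative to the scaling level. Scaled, the reference replicates lay at 2.725, 2.047 and 2.061.

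The cell envelope stress list, genes controlled by the CesSR 2-component system, had 11 members matched by locus tag; membership rests on a list fixed beforehand, not on the files. At 5 min of hexanol 2 members rose, 0 fell and 9 did not pass, with the same count adjusted over the list alone. The list mean was 0.45 higher (95% interval 0.01 to 0.88), and camera with a preset correlation gave an adjusted p of 5.7e-04. With an estimated correlation the adjusted p was 0.35. On the slide shared with the reference the list mean differed by -0.02, and with slide as a block by 0.22 (SE 0.201). At 5 min of ethanol and of butanol 0 members rose and 1 fell, and for ethanol the median (-0.06) and mean (0.03) differed in sign. At 60 min 0 members rose, while 2 fell with ethanol, 2 with butanol and 1 with hexanol. The list was lower at 60 min than at 5 min of hexanol by a mean of -0.65, with 4 members lower (camera adjusted p = 2.2e-05; adjusted p = 0.27 with an estimated correlation). Within the 2 slides that held both groups the difference was -1.04 and -0.72. Those slides did not hold replicate 1 of hexanol at 5 min, whose list mean was -0.419. Replicates 2 and 3 lay at 0.372 and 0.172, and the 60 min arrays at -0.668 and -0.55.

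**Figure D3:**
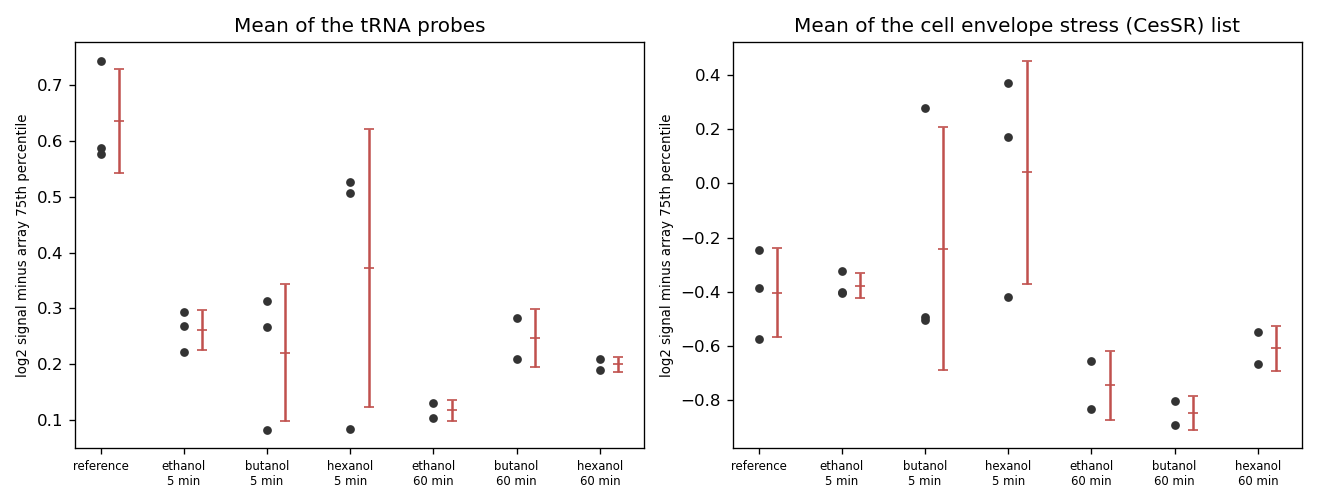
Mean level of the 231 tRNA probes (left) and of the 11 genes of the cell envelope stress list (right) on each array (points, log2 signal minus the array's 75th percentile), with the group mean and SD in red. The tRNA mean of each alcohol array lay below the lowest reference array (0.58), and the list mean spread widely between replicates of butanol and hexanol at 5 min.

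Of 105 phage-labelled features, 35 carried a TP901-1 number, 52 an sk1 number and 18 a short gene name. These labels do not show that the sequences lie in the genome of the strain. Of the 105 features, 81 were tested and 33 were well above background on all 18 arrays. The number called against the reference was 6 lower with ethanol at 5 min, 2 higher with hexanol at 5 min, 1 higher with butanol at 60 min and 0 in the other 3 comparisons. Camera with a preset correlation placed the set lower with ethanol at 5 min (adjusted p = 7.6e-04) and higher with hexanol at 5 min (adjusted p = 3.1e-05). With an estimated correlation these adjusted p were 0.88 and 0.35. The set means were -0.63 and 0.4, and the negative control spots moved the same way: they lay at -10.72 ± 0.25 in the reference, -11.69 ± 0.41 in ethanol and -9.86 ± 0.17 in hexanol at 5 min (SD, n = 3 each). Both directions turned with normexp correction (0.87 and -1.04), and that of hexanol also with quantile normalization (-0.08) and in the deposited values (-0.06).

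The alcohols are straight-chain molecules of increasing carbon chain length, and their doses differed, so the following comparisons are at matched times and unmatched doses. At 5 min, ethanol and butanol differed in 157 features, 76 higher and 81 lower with ethanol. llmg_1172 was 3.65-fold higher with ethanol (log2 difference 1.87, SE 0.123, limma adjusted p = 1.8e-07) and llmg_1171 3.46-fold higher. llmg_0372 was lower with ethanol by -0.94 (SE 0.081, adjusted p = 1.8e-06) and llmg_1138 by -0.81 (SE 0.221, adjusted p = 0.041). The adjusted p of llmg_1138 was 0.064 with slide as a block, 0.11 with median scaling, 0.083 with the brightest probe and between 0.054 and 0.19 when any 1 of the 6 arrays was left out. Of the 157 features, all had the same sign within each of the 3 slides, and 130 features were called with slide as a block. Without ethanol replicate 1, butanol replicate 1 or butanol replicate 2 the counts were 86, 103 and 91. Median scaling gave 61 higher and 38 lower, and normexp correction 68 and 45.

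Ethanol and hexanol at 5 min differed in 527 features, 200 higher and 327 lower with ethanol. llmg_0438 was 4.97-fold higher with ethanol, at 1 ± 0.18 against -1.32 ± 0.23 (SD, n = 3 each; log2 difference 2.31, SE 0.194, limma adjusted p = 7.8e-07), and llmg_1172 was 4.79-fold higher. llmg_0438 lay in a stretch of 5 tags with a mean difference of 1.34. Lower with ethanol were llmg_phage_rep (adjusted p = 0.013) and llmg_phage_TP901-1p47 (adjusted p = 5.1e-04). No fold is given for the former because of the outlier marks on its ethanol arrays: its difference was -1.07 with the marks ignored (adjusted p = 0.018) and -1.62 with probe offsets removed (adjusted p = 0.0039). By signal the latter was at least 1.23-fold lower, as no spot without an outlier mark was well above background with ethanol and 2 of the hexanol arrays held one. It lay at -11.62 with ethanol and -9.17 with hexanol, and the negative control spots at -11.69 and -9.86. The bound does not allow for this shift of the controls, so it is no lower bound for the transcript. The signs of both features turned with normexp correction (0.32 and 2.03). Neither feature passed in the deposited values (adjusted p = 0.05 and 0.16), nor llmg_phage_TP901-1p47 with the brightest probe (adjusted p = 0.18). In all, 34 phage-labelled features were called lower. Over the 81 tested, the mean difference was -1.03, and -1.07 with median scaling. It was 0 with quantile normalization, -0.03 in the deposited values and 1.91 with normexp correction. A fit without phage-labelled features called 198 higher and 291 lower. Normexp correction gave 95 higher and 256 lower. In the fit that blocked on slide, 480 features were called, and 527, 523 and 521 of the 527 had the same sign on the 3 slides.

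Butanol and hexanol at 5 min differed in 66 features, 20 higher and 46 lower with butanol. llmg_1676 was 2.55-fold higher with butanol (log2 difference 1.35, SE 0.13, limma adjusted p = 4.5e-05) and llmg_0317 2.16-fold higher. llmg_1049 was lower by -0.84 (SE 0.124, adjusted p = 0.0046) and llmg_1048 by -0.71. llmg_1490, which rose with both, differed by 0.22 (95% interval -0.04 to 0.47). The number of calls was 37 when slide was a block, within each of the 3 slides all 66 had the same sign, and without butanol replicates 1, 2 or 3 or hexanol replicate 1 the counts were 16, 16, 6 and 21. The adjusted p of llmg_1048 was 0.11, 0.067, 0.062 and 0.095 in these 4 fits. In a fit of the compared arrays alone it was 0.06, as for llmg_1049, and 0.065 for llmg_0317. Quantile normalization gave 35 higher and 47 lower, the deposited values 25 and 32, and normexp correction 13 and 58.

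At 60 min, ethanol and butanol differed in 190 features, 116 higher and 74 lower with ethanol. llmg_1676 was 3.4-fold higher with ethanol (log2 difference 1.76, SE 0.159, limma adjusted p = 4.3e-06). llmg_0973 was 3.26-fold higher, in a stretch of 5 tags with a mean difference of 1.46. llmg_0891 was lower by -1.59 (SE 0.154, adjusted p = 8.5e-06) and llmg_1508 by -1.31, the latter with an adjusted p of 0.057 in a fit of the compared arrays alone. A fit with slide as a block called 160 features, and on both slides that held the groups all 190 had the same sign. Without ethanol replicate 2, butanol replicate 1 or butanol replicate 2, 84, 116 and 79 were called.

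Ethanol and hexanol at 60 min differed in 168 features, 96 higher and 72 lower with ethanol. llmg_0973 was 3.96-fold higher with ethanol, at 0.61 ± 0.03 against -1.37 ± 0.2 (SD, n = 2 each; log2 difference 1.98, SE 0.139, limma adjusted p = 7.8e-07), and llmg_1171 was 3.74-fold higher. llmg_1516 was lower by -1.47 (SE 0.151, adjusted p = 1.7e-05) and llmg_0447 by -1.18; in a fit of the compared arrays alone their adjusted p were 0.053 and 0.074. The median of all features differed by -0.14, and median scaling gave 128 higher and 29 lower, normexp correction 79 and 137. Blocking on slide gave 150 calls, all 168 kept their sign on both slides, and without ethanol replicate 1, ethanol replicate 2 or hexanol replicate 2 the counts were 374, 76 and 105.

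Butanol and hexanol at 60 min differed in 4 features. llmg_2268 was 1.46-fold higher with butanol (log2 difference 0.54, SE 0.097, limma adjusted p = 0.036), and llmg_1576 and llmg_0751 were lower by -0.71 and -0.69. The count at an unadjusted p under 0.05 was 135. Of features that had changed against the reference in both groups, llmg_0975 differed by 0.21 (95% interval -0.16 to 0.58), llmg_1490 by -0.1 (95% interval -0.41 to 0.22) and llmg_2309 by -0.31 (95% interval -0.58 to -0.03, adjusted p = 0.73). In the fit that blocked on slide, 0 features were called, although all 4 had the same sign on both slides. Without butanol replicate 1, butanol replicate 2 or hexanol replicate 1 the count was 0, as with median scaling, normexp correction and a fit of the compared arrays alone. Whichever of the 4 arrays was left out, the call of llmg_2268 was lost. With the brightest probe the adjusted p of llmg_2268, llmg_1576 and llmg_0751 were 0.59, 0.26 and 0.29, and in the deposited values that of llmg_0751 was 0.069. Quantile normalization called 57 features, 46 higher and 11 lower, and the deposited values 47, 40 higher and 7 lower.

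Between 5 and 60 min of ethanol 450 features differed, 275 higher and 175 lower at 60 min. llmg_0446 was 4.95-fold lower at 60 min, at -1.02 ± 0.32 (SD, n = 2) against 1.29 ± 0.08 (SD, n = 3), with a log2 difference of -2.31 (SE 0.221, limma adjusted p = 2.7e-05). llmg_1901 was 3.61-fold lower, in a stretch of 7 tags with a mean difference of -1.16. The largest positive differences were phage-labelled, llmg_phage_bpp (2.06, adjusted p = 0.05) and llmg_phage_sk1p36 (1.5, adjusted p = 0.026), and both turned with normexp correction (-0.14 and -0.45). With quantile normalization they were 1.49 and 0.64 (adjusted p = 0.11 and 0.13) and in the deposited values 1.06 and 0.22 (adjusted p = 0.14 and 0.27), while llmg_phage_bpp was 0.91 with outlier marks ignored and 0.82 with probe offsets removed (adjusted p = 0.29 and 0.19). The brightest probes gave 0.06 and -0.15 (adjusted p = 0.96 and 0.87), and the adjusted p of llmg_phage_sk1p36 was 0.06 with slide as a block and 0.12 with the compared arrays alone. Of 5 fits that left out 1 array, the call of llmg_phage_bpp was lost in 5 (1.33, adjusted p = 0.29 without ethanol 60 min replicate 1) and that of llmg_phage_sk1p36 in 4. The negative control spots were 0.44 higher at 60 min (SE 0.519). Of the 239 features higher than the reference at 5 min, 186 were also higher at 60 min, and of the 355 lower ones 200 were also lower. The number of calls was 348 when slide was a block and all 450 had the same sign on both slides. Median scaling gave 170 higher and 292 lower, normexp correction 147 and 141, and without ethanol 60 min replicate 2 or 5 min replicate 1, 222 and 277 features were called. Without ethanol 60 min replicate 2 the adjusted p of llmg_1901 was 0.053.

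Between 5 and 60 min of butanol 212 features differed, 120 higher and 92 lower at 60 min. llmg_2309 was 3.02-fold higher at 60 min (log2 difference 1.6, SE 0.119, limma adjusted p = 2.4e-06) and llmg_2310 2.92-fold higher, in a stretch of 6 tags with a mean difference of 1.2. llmg_2164, a member of the cell envelope stress list, was 3-fold lower (-1.58, SE 0.304, adjusted p = 0.0038) and llmg_1575 was 2.91-fold lower. A fit with slide as a block called 154 features and all 212 had the same sign on both slides. Median scaling gave 66 higher and 101 lower. Without butanol 60 min replicates 1 or 2 or 5 min replicates 1 or 3 the counts were 105, 87, 126 and 141, and without 60 min replicate 2 the adjusted p of llmg_2164 was 0.054, and with the brightest probe 0.071.

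Between 5 and 60 min of hexanol 735 features differed, 482 higher and 253 lower at 60 min. llmg_2309 was 4.57-fold higher at 60 min, at 0.38 ± 0.18 (SD, n = 2) against -1.81 ± 0.18 (SD, n = 3), with a log2 difference of 2.19 (SE 0.119, limma adjusted p = 3.8e-08). llmg_2310 was 4.02-fold higher, and both lay in a stretch of 8 tags with a mean difference of 1.42. llmg_2164 was 2.97-fold lower and llmg_1901 2.83-fold lower. The arrays also differed in signal range: the SD of log2 gene probe signals was 1.033 ± 0.015 at 5 min (SD, n = 3) and 0.77 ± 0.112 at 60 min (SD, n = 2), and the median gene probe signal 46361 and 90541. The median of all features was 0.17 higher at 60 min, and the split turned under other processing: 194 higher and 290 lower with quantile normalization, 143 and 382 with median scaling, 101 and 150 with normexp correction and 164 and 268 in the deposited values. Blocking on slide gave 509 calls, and 728 and 735 of the 735 had the same sign on the 2 slides. Without hexanol 60 min replicate 2 or 5 min replicate 1, 252 and 453 were called, and without the former the adjusted p of llmg_1901 was 0.088, and 0.061 in a fit of the compared arrays alone.

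The change from 5 to 60 min differed between ethanol and butanol in 57 features, between ethanol and hexanol in 133 and between butanol and hexanol in 12. llmg_0973 was 1.58 higher on the log2 scale in the ethanol than in the butanol time course (SE 0.179, limma adjusted p = 2.6e-04). The change of llmg_0446 was more negative with ethanol than with butanol (-1.61, SE 0.313, adjusted p = 0.012) and than with hexanol (-2.64, SE 0.313, adjusted p = 1.3e-04). With ethanol this change was -2.31, so the fitted change with hexanol was not a fall. The adjusted p of llmg_0446 against butanol was 0.085 without ethanol 60 min replicate 2 and 0.07 without butanol 60 min replicate 1. Counts with slide as a block were 48, 100 and 5, and leaving out 1 array gave 17 to 81, 59 to 491 and 3 to 18. The split of the ethanol and hexanol contrast, 79 higher and 54 lower, was 86 and 31 with median scaling, and that of ethanol and butanol, 40 and 17, was 71 and 48 in the deposited values. The split of the butanol and hexanol contrast, 5 higher and 7 lower, was 34 and 19 with quantile normalization, 29 and 16 in the deposited values, 0 and 2 with median scaling and 0 and 4 with normexp correction.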

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

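The tests of the scaling for hexanol and of compression in the separate 5 min groups, the slide block with other processing and the fit with outlier marks ignored were chosen only after the result was seen.

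The change from 5 to 60 min differed between ethanol and butanol in 57 features and between ethanol and hexanol in 133, by the interaction test of the fit. It differed between butanol and hexanol in 12. Among the named features with a spot above background in each group, the largest such differences were 1.72 on the log2 scale for llmg_1138 (ethanol against butanol), -2.64 for llmg_0446 (ethanol against hexanol) and -1.51 for llmg_0317 (butanol against hexanol). The adjusted p of llmg_1138 rose above 0.05 in 3 fits that left out 1 array, and was 0.072 with the brightest probe. That of llmg_0317 did so in 6, and was 0.06 with median scaling, 0.16 with normexp correction and 0.053 with slide as a block. llmg_phage_TP901-1p47 was also called between ethanol and hexanol, but had no unmarked spot well above background in ethanol at 5 min, so no size is given. Its adjusted p was 0.19 with outlier marks ignored, 0.25 with the brightest probe, 0.94 with normexp correction and 0.36 in the deposited values. The phage-labelled set differed by a mean of 0.5 between ethanol and butanol, 1.13 between ethanol and hexanol and 0.63 between butanol and hexanol, and the cell envelope stress list by 0.28 between ethanol and hexanol. These 4 set differences passed camera with a preset correlation, and with an estimated one the adjusted p were 0.53, 0.22, 0.43 and 0.36. The negative control spots gave 0.79, 1.16 and 0.37 for the 3 phage-labelled differences (SE 0.733). The set differences themselves were 0.03, 0.19 and 0.16 with quantile normalization, -0.05, 0.18 and 0.23 in the deposited values and 1.5, 0.18 and -1.33 with normexp correction.

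At 60 min of hexanol 65.6% of the called features were higher than at 5 min, and leaving out 1 array gave shares from 44.4% to 74.1%. With quantile normalization the share was 40.1%, but that setting also moved the median of all features by -0.172, and since centring can set the share, it decides nothing about the signal range of the arrays. With slide as a block it was 60.5%, within the range over single arrays. The groups differed in signal range, with an SD of log2 gene probe signals of 1.033 ± 0.015 at 5 min and 0.77 ± 0.112 at 60 min. The scaling, the slide and a change in the cells at 60 min all stay open.

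The 34 phage-labelled features called lower in ethanol than in hexanol at 5 min had a median log2 difference of -1.56. The negative control spots differed by -1.83 in the same direction (-11.69 ± 0.41 against -9.86 ± 0.17, SD, n = 3 each), so the background level of the arrays is a possible explanation. Each of the 3 slides held 1 array of both groups, so an offset shared by the arrays of a slide cancels in this difference; over all 81 tested phage-labelled features the medians within the slides were -1.09, -1.7 and -0.39. The mean difference over these 81 features was -1.03, and -1.07 with median scaling. It was 0 with quantile normalization, -0.03 in the deposited values and 1.91 with normexp correction. Of the 34 features, 7 were well above background on all 6 arrays by a spot without an outlier mark. A difference in phage transcripts was not tested apart from the background.

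The tRNA probes were lower than the reference in each alcohol group. Their fall beyond that of gene probes matched on reference level was 0.27 with ethanol and with butanol at 5 min (SD between arrays 0.07 and 0.09), which argues against compression of bright probes as the whole cause in these 2 groups. Compression stays open at 60 min, where the smallest extra fall was 0.06 (butanol). It also stays open for hexanol at 5 min, where the extra fall was 0.3 with an SD of 0.23. Replicate 2 carried much of it, at 0.57 against 0.17 for replicates 1 and 3. In hexanol at 5 min the matched gene probes did not fall (0.03), and each array lay above the highest reference array (0.07). On the slide of the reference 1 array of each alcohol at 5 min lay at -0.34, -0.37 and -0.13 against a reference SD of 0.09, no 60 min array shared it, and with slide as a block the highest unadjusted p at 60 min was 0.068 (butanol). With that block butanol at 5 min (-0.34, adjusted p = 0.034) and ethanol at 60 min (-0.41, adjusted p = 0.038) still passed, but with other processing the adjusted p ranged from 0.017 to 0.068 and from 0.045 to 0.067, so the slide and a fall of tRNA in the cells stay open in all 6 groups.

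For the 6 comparisons of 3 against 3 arrays, the real split gave the most calls, 1 of 10 splits in each. The highest other split gave 11 for butanol against hexanol (real 66) and 0 for the other 5 comparisons. Each other split mixed arrays of both groups, which put any difference between the groups into the spread of the fit. Few calls from such splits were therefore likely beforehand and say little about chance. With 10 splits no share under 0.05 can be reached.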

How the results depend on the processing

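The fits without phage-labelled features, without both arrays of extreme signal range (reference replicate 1 and hexanol 60 min replicate 2), with outlier marks ignored and with probe offsets removed were chosen after seeing the data. Of 1320 values of named features under the alternatives, 1174 kept their direction and their side of the threshold, 141 kept their direction and were no longer past it, and 5 reversed. With normexp correction llmg_phage_rep (0.32) and llmg_phage_TP901-1p47 (2.03) reversed for ethanol against hexanol at 5 min, and llmg_phage_bpp (-0.14) and llmg_phage_sk1p36 (-0.45) for ethanol at 60 against 5 min; llmg_phage_sk1p36 also reversed with the brightest probe (-0.15). Of 466 counts, 320 lay within 1.5 times the main count. The causes of the other changes were not tested, and low signal over background limits the phage-labelled features. Median shifts of all features over 0.1 against the main scaling arose with quantile normalization in ethanol against hexanol at 60 min (0.12), 60 min against 5 min of hexanol (-0.172) and the interactions of ethanol (0.17) and butanol (0.141) against hexanol. In the deposited values these 4 were 0.126, -0.171, 0.177 and 0.153, and with median scaling 0.11, -0.196, 0.147 and 0.143, with -0.135 for hexanol 60 min. With normexp correction they were -0.123 for butanol 5 min, -0.136 and -0.141 for ethanol against hexanol at 5 and 60 min, -0.21 for butanol against hexanol at 5 min, 0.113 for 60 min against 5 min of butanol and -0.113 for the interaction of ethanol against butanol.

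With quantile normalization the number of calls became 318 for ethanol against butanol at 60 min, 325 for ethanol against hexanol at 60 min, 57 for butanol against hexanol at 60 min, 334 for 60 min against 5 min of butanol, 484 for 60 min against 5 min of hexanol, 140 for the interaction of ethanol against butanol, 263 for the interaction of ethanol against hexanol, 53 for the interaction of butanol against hexanol and 5 for gene list shifts. With median scaling the number of calls became 99 for ethanol against butanol at 5 min, 21 for butanol against hexanol at 5 min, 0 for butanol against hexanol at 60 min and 2 for the interaction of butanol against hexanol. Under normexp correction the number of calls became 210 for hexanol 5 min, 351 for ethanol against hexanol at 5 min, 0 for butanol against hexanol at 60 min, 288 for 60 min against 5 min of ethanol, 251 for 60 min against 5 min of hexanol, 69 for the interaction of ethanol against hexanol and 4 for the interaction of butanol against hexanol. In the deposited values the number of calls became 301 for ethanol against butanol at 60 min, 296 for ethanol against hexanol at 60 min, 47 for butanol against hexanol at 60 min, 432 for 60 min against 5 min of hexanol, 119 for the interaction of ethanol against butanol, 226 for the interaction of ethanol against hexanol, 45 for the interaction of butanol against hexanol and 5 for gene list shifts. For the brightest probe the number of calls became 94 for ethanol against butanol at 5 min, 37 for butanol against hexanol at 5 min, 124 for ethanol against butanol at 60 min, 121 for 60 min against 5 min of butanol, 33 for the interaction of ethanol against butanol and 2 for the interaction of butanol against hexanol.

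Blocking on slide as a fixed factor, the number of calls became 465 for ethanol 60 min, 244 for butanol 60 min, 264 for hexanol 60 min, 37 for butanol against hexanol at 5 min, 0 for butanol against hexanol at 60 min and 5 for the interaction of butanol against hexanol. With slide as a random block the number of calls became 5 for the interaction of butanol against hexanol. Under limma's trend and robust option the number of calls became 114 for butanol against hexanol at 5 min and 7 for butanol against hexanol at 60 min. At an adjusted p under 0.05 and at least 2-fold, the number of calls became 63 for ethanol 5 min, 26 for butanol 5 min, 24 for hexanol 5 min, 118 for ethanol 60 min, 51 for butanol 60 min, 63 for hexanol 60 min, 19 for ethanol against butanol at 5 min, 69 for ethanol against hexanol at 5 min, 3 for butanol against hexanol at 5 min, 33 for ethanol against butanol at 60 min, 33 for ethanol against hexanol at 60 min, 0 for butanol against hexanol at 60 min, 35 for 60 min against 5 min of ethanol, 26 for 60 min against 5 min of butanol, 39 for 60 min against 5 min of hexanol, 21 for the interaction of ethanol against butanol, 35 for the interaction of ethanol against hexanol, 3 for the interaction of butanol against hexanol, 14 for calls shared by ethanol 5 min and butanol 5 min, 14 for calls shared by ethanol 5 min and hexanol 5 min, 15 for calls shared by butanol 5 min and hexanol 5 min, 29 for calls shared by ethanol 60 min and butanol 60 min, 43 for calls shared by ethanol 60 min and hexanol 60 min and 39 for calls shared by butanol 60 min and hexanol 60 min. At an adjusted p under 0.01 the number of calls became 324 for butanol 5 min, 215 for hexanol 5 min, 502 for ethanol 60 min, 337 for butanol 60 min, 349 for hexanol 60 min, 80 for ethanol against butanol at 5 min, 292 for ethanol against hexanol at 5 min, 12 for butanol against hexanol at 5 min, 103 for ethanol against butanol at 60 min, 79 for ethanol against hexanol at 60 min, 0 for butanol against hexanol at 60 min, 216 for 60 min against 5 min of ethanol, 60 higher and 47 lower (1.1e+02 in all) for 60 min against 5 min of butanol, 310 for 60 min against 5 min of hexanol, 21 for the interaction of ethanol against butanol, 52 for the interaction of ethanol against hexanol and 3 for the interaction of butanol against hexanol. With only the arrays of the groups compared the number of calls became 442 for ethanol 60 min, 197 for hexanol 60 min, 3 for butanol against hexanol at 5 min, 40 for ethanol against butanol at 60 min, 17 for ethanol against hexanol at 60 min, 0 for butanol against hexanol at 60 min, 213 for 60 min against 5 min of ethanol, 215 for 60 min against 5 min of hexanol, 44 for the interaction of ethanol against hexanol and 4 for the interaction of butanol against hexanol. Without both arrays of extreme signal range the number of calls became 338 for hexanol 60 min, 159 for butanol against hexanol at 5 min, 298 for 60 min against 5 min of hexanol and 5 for the interaction of butanol against hexanol. With an estimated inter-gene correlation the number of calls became 0 for gene list shifts. With fry the number of calls became 1 for gene list shifts.

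Replicate numbers showed no clear pairing of the arrays: over 48 same-numbered pairs the correlation of deviations from the group means ranged from -0.4 to 0.43 (median -0.02, 20 over 0.1), and 8 of 18 arrays were closest to their own number. In groups this small the deviations within a group depend on each other, so the check cannot exclude shared cultures. The labels do not state whether same-numbered samples came from one culture. With replicate number as a block the number of calls became 35 for butanol against hexanol at 5 min, 2 for butanol against hexanol at 60 min and 5 for the interaction of butanol against hexanol; other counts stayed within 1.5 times.

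Leaving out 1 array gave 12 to 16 for gene list shifts, 375 to 476 for butanol 5 min, 282 to 551 for butanol 60 min, 485 to 567 for ethanol 5 min, 511 to 747 for ethanol 60 min, 256 to 376 for hexanol 5 min, 389 to 692 for hexanol 60 min, 87 to 147 for 60 min against 5 min of butanol, 222 to 438 for 60 min against 5 min of ethanol, 252 to 1021 for 60 min against 5 min of hexanol, 6 to 64 for butanol against hexanol at 5 min, 0 to 5 for butanol against hexanol at 60 min, 86 to 119 for ethanol against butanol at 5 min, 79 to 230 for ethanol against butanol at 60 min, 363 to 545 for ethanol against hexanol at 5 min, 76 to 374 for ethanol against hexanol at 60 min, 3 to 18 for the interaction of butanol against hexanol, 17 to 81 for the interaction of ethanol against butanol and 59 to 491 for the interaction of ethanol against hexanol. A lone remaining array was assumed to vary like the other groups.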

Other observations

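The features below were chosen after their values were seen, and all tests here are those of the fit. llmg_2309 was 1.61 above the reference at 5 min of ethanol (95% interval 1.39 to 1.84), where butanol gave 0.09 (-0.13 to 0.32) and hexanol -0.19 (-0.42 to 0.03). At 60 min the values were 2.57, 1.69 and 2. llmg_0975 was below the reference at 5 min of ethanol by -0.81, and at 60 min by -0.19 (-0.53 to 0.15). With butanol it went from -1.08 to -1.75 and with hexanol from -1.2 to -1.96. The change over time differed between ethanol and butanol by 1.29 (0.81 to 1.77) and between butanol and hexanol by 0.09 (-0.39 to 0.58). llmg_1676 was 1.52 above the reference at 5 min of ethanol and 1.27 at 5 min of butanol, against -0.09 with hexanol (-0.36 to 0.19). At 60 min it was 1.89 with ethanol, 0.12 with butanol (-0.19 to 0.43) and 0.23 with hexanol (-0.08 to 0.53).

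Of the 186 features higher and 181 lower at 5 min of hexanol, 96 and 98 were called in the same direction at 60 min. For butanol these numbers were 126 of 213 and 172 of 285. The 5 probes of unexplained name had median signals from 13440.2 to 58838.2 over the arrays and were well above background on each.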
